A study of Mus musculus with 120 samples.

How the data were processed

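RNA from 120 libraries of mouse bone-marrow-derived macrophages was measured by 3′ digital gene expression. Per the labels' protocols, cells carried a transcription factor reporter virus, were replated in multiwell format, lysed and purified on beads. Libraries were made by modified SCRB-Seq with DNase treatment, reverse transcription, second strands from random hexamers and a modified Nextera step. The deposited table gives, per the labels, a raw count for each of 23481 gene symbols in each library, which the authors made from reads that the submitters' processing notes link to BWA and the mm10 genome. The versions, the counting program, its annotation, the strand setting and the use of molecular identifiers are not given in the sources used here. No column was scaled, since totals differ, and no row was without a gene name. The unit of the time labels, the exposure before T0 and the proline status of controls are not given either.

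The 45 groups were 12 controls at each of T0, T1 and T4, and 2 libraries for each of 7 doses, with and without 2 mM proline, at each time. Totals ran from 20000 to 114061 counts with a median of 49515, and 8 libraries had under 30000. Rn45s held 49.6% of all counts and Lars2 2.86%. No symbol of a mitochondrially encoded gene was present, so the planned mitochondrial share could not be computed, and the shares of Rn45s and Lars2 were used instead. Neither is a mitochondrially encoded gene, so these shares do not measure mitochondrial RNA. Gene positions, exon lengths and biotypes came from the GENCODE M21 annotation of GRCm38. Replicate libraries were compared in 240 pairs, and none were identical.

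Counts were tested in R 4.3.3 with edgeR 4.0.16, using quasi-likelihood fits, TMM scaling and the filterByExpr rule with a minimum count of 10 over the libraries of each fit. Adjusted p-values are Benjamini-Hochberg values within a comparison, with a threshold of 0.05, and tests are two-sided. Each SE given is the absolute log2 fold change divided by the square root of the test's F statistic. It is not a fitted standard error, and can be too small where a group has few counts. In all, 20 comparisons were made. LPS was tested as T1 or T4 controls against T0 controls, 12 libraries each, in 1 fit of 36. At each time, another fit of 40 libraries gave halofuginone against control, halofuginone with proline against control, and with against without proline, each treated side being the mean of 625, 2500 and 10000 nM (6 libraries). A further fit of 36 libraries tested the change from control at T1 or T4 less that at T0. Dose slopes in log2 per 10-fold dose used the 14 treated libraries of a time and arm, without controls. Levels are CPM on a TMM scale over all libraries, and log2 levels used a prior count of 3. No fold is given where the counts of a group were at or under a floor of 3. A symbol was tested only where it passed the filter, so counts of changed genes depend on depth. A gene low in 1 group can pass through another group where it is high. Counts of changed genes among the tested members of a list therefore lean towards that direction.

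In total, 24 gene lists were fixed before the counts were examined: targets of ATF4, tRNA synthetases, proline metabolism, inflammatory, interferon-stimulated and immediate early genes, cholesterol biosynthesis, endoplasmic reticulum chaperones, heat shock, NRF2, hypoxia and glycolysis, p53, cell cycle, lysosome, TGF-beta response, macrophage identity, neutrophil, B cell, T and NK cell, dendritic, erythroid and mast cell, fibroblast markers, ribosomal proteins and mitochondrially encoded genes. Lists with at least 3 tested members were tested with camera in limma 3.58.1 at its preset correlation, again with an estimated correlation, and with fry. Members were also counted with p-values adjusted over the list alone. Lists share some genes.

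Genes are named by a rule fixed beforehand. It takes the 6 largest increases and the 6 largest decreases with an adjusted p under 0.05, an average level at or above the median and every treated library on the same side of the other group's mean, leaving out symbols of predicted genes and pseudogenes. It adds up to 4 members of each list with the smallest adjusted p, and 14 genes that are always reported, such as Eprs, Atf4, Tnf and Il6. A few genes that the rule takes are not reported here. Single-dose comparisons were added after the data had been examined.

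Library measures (total counts, counts without Rn45s, genes with a count, and the shares of Rn45s and Lars2) were compared between 6 treated and 12 control libraries by exact two-sided permutation of the labels, adjusted over 30 tests. Alternatives were median-of-ratios scaling, no filter on low counts, DESeq2 1.42.0, replicate number as a block, no 10000 nM dose and each library left out in turn. Added after the data had been examined were fits without libraries under 30000 counts and without Rn45s, Lars2, Rn4.5s, Rnu6, Rpph1 and Rmrp. Libraries were treated as unpaired. By a rule fixed beforehand, single outlying libraries were to be tested only in groups of 4 to 10, and the groups here have 2 or 12.

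The procedure was tested on simulated data with known changes. Changes of 4-fold were recovered in 100% of genes for LPS at T4, 93.7, 95.2 and 90.2% for halofuginone at T0, T1 and T4, 88.5% for proline at T4 and 78.7% for the change in the LPS response at T4. Changes of 2-fold were recovered in 96.7, 55.7, 46.6, 43.9, 39.3 and 26.3%. False calls were 4.28, 7.14, 11.9, 5.41, 4.93 and 9.56% of the calls, above the nominal 5% in 4 of these 6 settings. Rn45s was kept out of the simulated changes after a first simulation gave more false calls. In the real libraries its share does change with halofuginone, so the shares of false calls there may be too low. Many genes were changed at once, which makes recovery easier than where few genes change. Camera called none of 20 unchanged lists in any setting, while fry called 7, 13 and 11 of 20 for halofuginone at T0, T1 and T4, and is not relied on there.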

Results

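The series holds 120 RNA libraries from bone-marrow-derived macrophages of male C57BL/6 mice, grown from wild-type marrow and carrying a virus that reports transcription factor activity. Bacterial lipopolysaccharide (LPS) is sensed by macrophages through Toll-like receptor signalling. By the series design cells had halofuginone for 30 minutes before LPS, while the treatment protocol speaks of a dose curve over 4 hours, with LPS or without it. Halofuginone blocks the prolyl-tRNA synthetase site of the enzyme encoded by Eprs, so that proline competes with it. Each library carries 1 of 3 time labels, 0, 1 or 4, which have no unit and are called T0, T1 and T4 here. No label says which libraries received LPS, so T1 and T4 are read as times after LPS from the series design. At each time there were 12 control libraries and, for each of 7 doses from 2.4 to 10000 nM, 2 libraries with halofuginone alone and 2 with 2 mM proline added, which makes 45 groups. The question addressed here is how halofuginone changes macrophage mRNAs at rest and after LPS, and whether proline changes that effect. The 2 statements leave open how long T0 cells had been exposed to halofuginone, and controls carry no proline label, so proline by itself could not be separated. Nothing in the labels says that replicates are separate cultures, so every p-value measures only the spread between these libraries.

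The libraries count the 3′ ends of transcripts and are shallow. Totals ran from 20000 to 114061 counts, with a median of 49515, and 1761 to 6770 genes had a count. Rn45s, the ribosomal precursor RNA, had the highest count in all 120 libraries and took 27.0 to 71.1% of counts, which left 5798 to 69316 counts for all other genes. One count table with symbols was deposited. Levels below are scaled counts (CPM) on 1 scale over all libraries, as mean ± SD, while fold changes come from each comparison's own scaling, so a ratio of levels can differ from the fitted fold. The use of molecular identifiers is not stated, so intervals and floors cover counting error only. Unless another tool is named, adjusted p-values are two-sided, from edgeR. SE is derived from the fold change and the F statistic, and can be too small where 1 side has few counts.

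In controls, LPS raised cytokine mRNAs at T1. Il1b, which encodes the fever-inducing cytokine interleukin-1 beta, rose from 16.9 ± 21.1 to 2399 ± 340 CPM (log2 fold change 6.89, SE 0.20, adjusted p = 1.93e-42, 12 libraries against 12). The neutrophil-attracting chemokine Cxcl2 rose by 6.65 log2 (SE 0.22), the monocyte chemokine Ccl4 by 6.00 (SE 0.17), Cxcl10, which draws T cells, by 5.82 (SE 0.23) and Tnf, the first cytokine of many inflammatory reactions, by 5.80 (SE 0.28). Of 708 genes tested, 129 rose and 58 fell (136 and 28 with median-of-ratios scaling, 136 and 35 with DESeq2).

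Of 29 tested NF-kB and inflammatory response genes, 28 rose at T1 (28 when adjusted over the list alone), with a median of 3.60 log2. They include Nfkbia (3.55), which encodes the inhibitor that shuts NF-kB off again, and Tnfaip2 (3.60). All 5 tested immediate early genes rose, among them Junb (2.70), Dusp1 (3.49), Zfp36 (2.43) and Klf6 (1.97). In both lists, members low at T0 could pass the filter only through a later time, which favours a count of risers. Among 28 interferon-stimulated genes 12 rose and 1 fell (13 and 1 when adjusted over the list alone), led by Cxcl10, Ifit1 (3.03) and Rsad2 (2.62), and camera called that list (adjusted p = 0.00729; adjusted p = 0.0419 with an estimated correlation). Ribosomal protein mRNAs had a median of -0.22, with 11 of 76 lower (5 when adjusted over the list alone). Camera called them lower (adjusted p = 1.49e-05), but adjusted p = 0.109 with an estimated correlation. The lysosome list (5 lower and 1 higher of 12, 7 and 1 when adjusted over the list alone) and the macrophage identity list (2 lower and 1 higher of 15, 1 and 1 when adjusted over the list alone) were not called, with adjusted p = 0.0899 and 0.0934.

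By T4 the interferon programme led in controls. The antiviral gene Rsad2 rose from 91.8 to 15771 CPM (7.26, SE 0.14), Ifit1, whose product binds foreign RNA, from 41.0 to 5003 ± 597 CPM (6.73, SE 0.18) and Cxcl10 from 11.7 to 5017 ± 660 CPM (8.34, SE 0.19). The chemokines Ccl5 (7.11, SE 0.20) and Ccl3 (6.92, SE 0.23) and the mitochondrial kinase gene Cmpk2 (7.60, SE 0.26) rose as well. Il1b stayed high at 2993 ± 407 CPM, while Tnf was at 332 ± 87.8 CPM, under its 727 ± 116 at T1. The receptors Lrp1 (-2.49, SE 0.16), Nrp1 (-2.25, SE 0.21) and Csf1r (-1.21, SE 0.12) fell. Of 708 genes tested, 259 rose and 281 fell, but with median-of-ratios scaling 286 rose and 197 fell, and with DESeq2 289 and 201, so which direction holds more genes depends on the scaling.

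All 28 tested interferon-stimulated genes rose at T4 (28 when adjusted over the list alone, median 5.11 log2), as did 28 of 29 inflammatory genes (28, median 4.31). The filter favours these counts, since members low at T0 could be tested only through a later time. In controls all 40 listed interferon-stimulated genes summed to 1205 CPM at T0 and 47272 CPM at T4, and all 50 listed inflammatory genes to 1419 and 27840 CPM. Ribosomal protein mRNAs were lower in 68 of 76 (71 when adjusted over the list alone, median -0.52), for example Rpl10 (-0.71), and lysosomal mRNAs in 9 of 12 (9), for example Ctsd (-1.02) and Ctsl (-1.25). All 5 immediate early genes stayed higher (5). Camera called the last 3 lists, but each had adjusted p = 0.0545 with an estimated correlation. Macrophage identity genes split into 9 lower and 3 higher of 15 (9 and 3 when adjusted over the list alone, camera adjusted p = 0.0540), with the LPS co-receptor Cd14 higher (1.74). Another scaling, by median of ratios, moved the median of all genes in this comparison from -0.14 to 0.05. The tested TGF-beta response genes had a median of -0.13 on the first scale, 0.07 on the second, and camera's direction was upward (adjusted p = 0.881). Il6, Il12b, Nos2 and Ifnb1 had too few counts to be tested here. Il6 went from 0 counts in the 12 T0 controls to 287 in the 12 T4 controls, Il12b from 1 to 206 and Nos2 from 0 to 84, while Ifnb1 had 0, 21 and 2 counts at T0, T1 and T4.

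Halofuginone changed the composition of the libraries at every time. With 625, 2500 and 10000 nM pooled (6 libraries against 12 controls), Rn45s took 62.3 ± 1.17% of counts against 47.7 ± 3.21% at T0, 62.8 ± 2.31% against 43.6 ± 4.51% at T1 and 64.6 ± 2.22% against 38.0 ± 4.76% at T4. Each of these exact two-sided permutation tests gave p = 0.000108 (adjusted p = 0.000180 over 30 tests), the smallest they can give. The number of genes with a count was 3819 ± 358 against 5724 ± 502 at T0 and 2960 ± 428 against 5506 ± 469 at T4. Total counts were lower too, at 40219 ± 6661 against 56095 ± 12353 at T0 and 44764 ± 11597 against 75617 ± 19587 at T4. Fewer counts give fewer genes with a count, and no number of genes at equal depth was taken, so this drop does not show a loss of expressed genes. With proline the shares of Rn45s were 59.9 ± 2.72%, 61.9 ± 1.71% and 65.1 ± 3.05%. These shares are a background to each halofuginone comparison that follows.

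**Figure D1:**
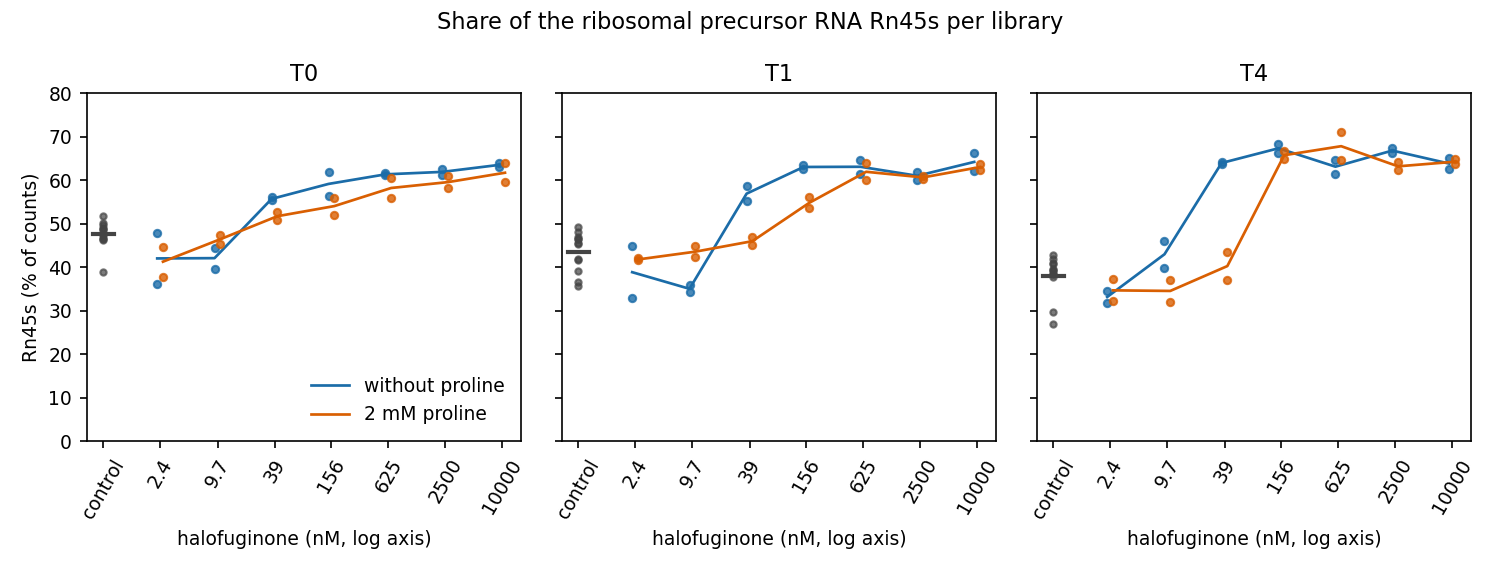
Share of each library's counts taken by Rn45s (%) against halofuginone dose (nM, log axis) at T0, T1 and T4, with points for libraries, lines through the means of 2 libraries with and without 2 mM proline, and a bar at the mean of the 12 controls. At T4 the mean of the 3 highest doses lies at 64.6% without proline and 65.1% with it, against 38.0% in controls.

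At T0, halofuginone alone raised inflammatory and immediate early mRNAs. Cxcl2 rose from 28.0 ± 29.5 CPM in 12 controls to 2979 ± 772 CPM in the 6 libraries at 625 nM and above (log2 fold change 6.60, SE 0.25, adjusted p = 1.85e-39). Ccl4 rose by 4.79 (SE 0.32), Tnf by 4.45 (SE 0.52, 269 against 10.0 CPM) and Il1b by 4.26 (SE 0.43). The histone demethylase gene Kdm6b (5.13, SE 0.36), the interferon-related regulator Ifrd1 (4.89, SE 0.30), the phosphatase Dusp1 (4.72, SE 0.38) and the stress gene Gadd45b (4.60, SE 0.35) were among the strongest. The chemokine receptor gene Ccr2 (-3.74, SE 0.69), S100a6 (-3.16, SE 0.46), the ribosomal protein gene Rpl37a (-3.14, SE 0.33) and the transcription factor Maf (-2.93, SE 0.43) fell. Of 1130 genes tested, 168 rose and 265 fell, and without a filter on low counts 127 and 434.

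Of 12 tested immediate early genes all 12 rose (12 when adjusted over the list alone, median 3.21), and of 19 inflammatory genes 14 rose and 5 did not pass (15 when adjusted over the list alone, median 3.98), including Nfkbia (3.14) and the activation marker Cd83 (3.09). Members low in controls could pass the filter only through treated libraries, which favours a count of risers. All 23 listed immediate early genes summed to 902 CPM in controls and 7883 CPM with halofuginone, and all 50 listed inflammatory genes to 1419 and 11168 CPM. Of 40 interferon-stimulated genes 2 were tested, and the list summed to 1140 ± 258 CPM with halofuginone and 1205 ± 266 CPM in controls. Cxcl10 had 6 counts in the 6 treated and 9 in the 12 control libraries. Targets of ATF4, the factor that cells translate when amino acids run short, rose in 7 of 10 and fell in 1 (8 and 1 when adjusted over the list alone, median 2.12). Atf4 itself went from 63.3 to 288 CPM (2.16, SE 0.37), Atf3 rose by 3.31 (SE 0.26), the stress factor Ddit3 by 2.59 (SE 0.55) and Cebpb by 2.13 (SE 0.37). Asns, Trib3 and Chac1, other targets of ATF4, had 3, 1 and 0 counts in the treated libraries and were not tested. In controls the 38 listed targets summed to 848 ± 104 CPM at T0 and 1674.5 ± 344 CPM at T1. A rise of this list is therefore not particular to a shortage of amino acids. Of 5 TGF-beta response genes 4 rose (4 when adjusted over the list alone, median 1.32), among them the differentiation inhibitors Id2 (2.28) and Id3 (2.30). Ribosomal protein mRNAs were lower in 64 of 77 (68 when adjusted over the list alone, median -1.22), for example Rpl41 (-2.12). Camera called these 5 lists, and all 5 calls held with an estimated correlation.

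Other groups at T0 did not pass the list test. Macrophage identity genes were lower in 7 of 15 (7 when adjusted over the list alone, adjusted p = 0.0579), for example Lpl (-0.90) and Apoe (-0.94). Lysosomal genes were lower in 7 and higher in 1 of 13 (9 and 1 when adjusted over the list alone, adjusted p = 0.0579), with Ctsb at -1.08 and the autophagy receptor Sqstm1 at 1.46. Of 3 p53 targets Mdm2 (1.98) and Plk2 (3.51) rose (2 when adjusted over the list alone, adjusted p = 0.0579). Of 4 NRF2 targets the ferritin gene Ftl1 (-1.13) and Prdx1 (-1.82) fell (2, adjusted p = 0.0813). Of 8 hypoxia and glycolysis genes 3 fell (3, adjusted p = 0.383), of 3 heat shock genes 1 rose and 1 fell (1 and 1, adjusted p = 0.770), and none of 5 endoplasmic reticulum chaperone genes passed (0, adjusted p = 0.770). None of 4 tested tRNA synthetase genes passed (0, median 0.08, adjusted p = 0.880), and Eprs, whose product is the target of the drug, was at 100 against 96.1 CPM (0.07, SE 0.48, adjusted p = 0.914).

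**Figure D2:**
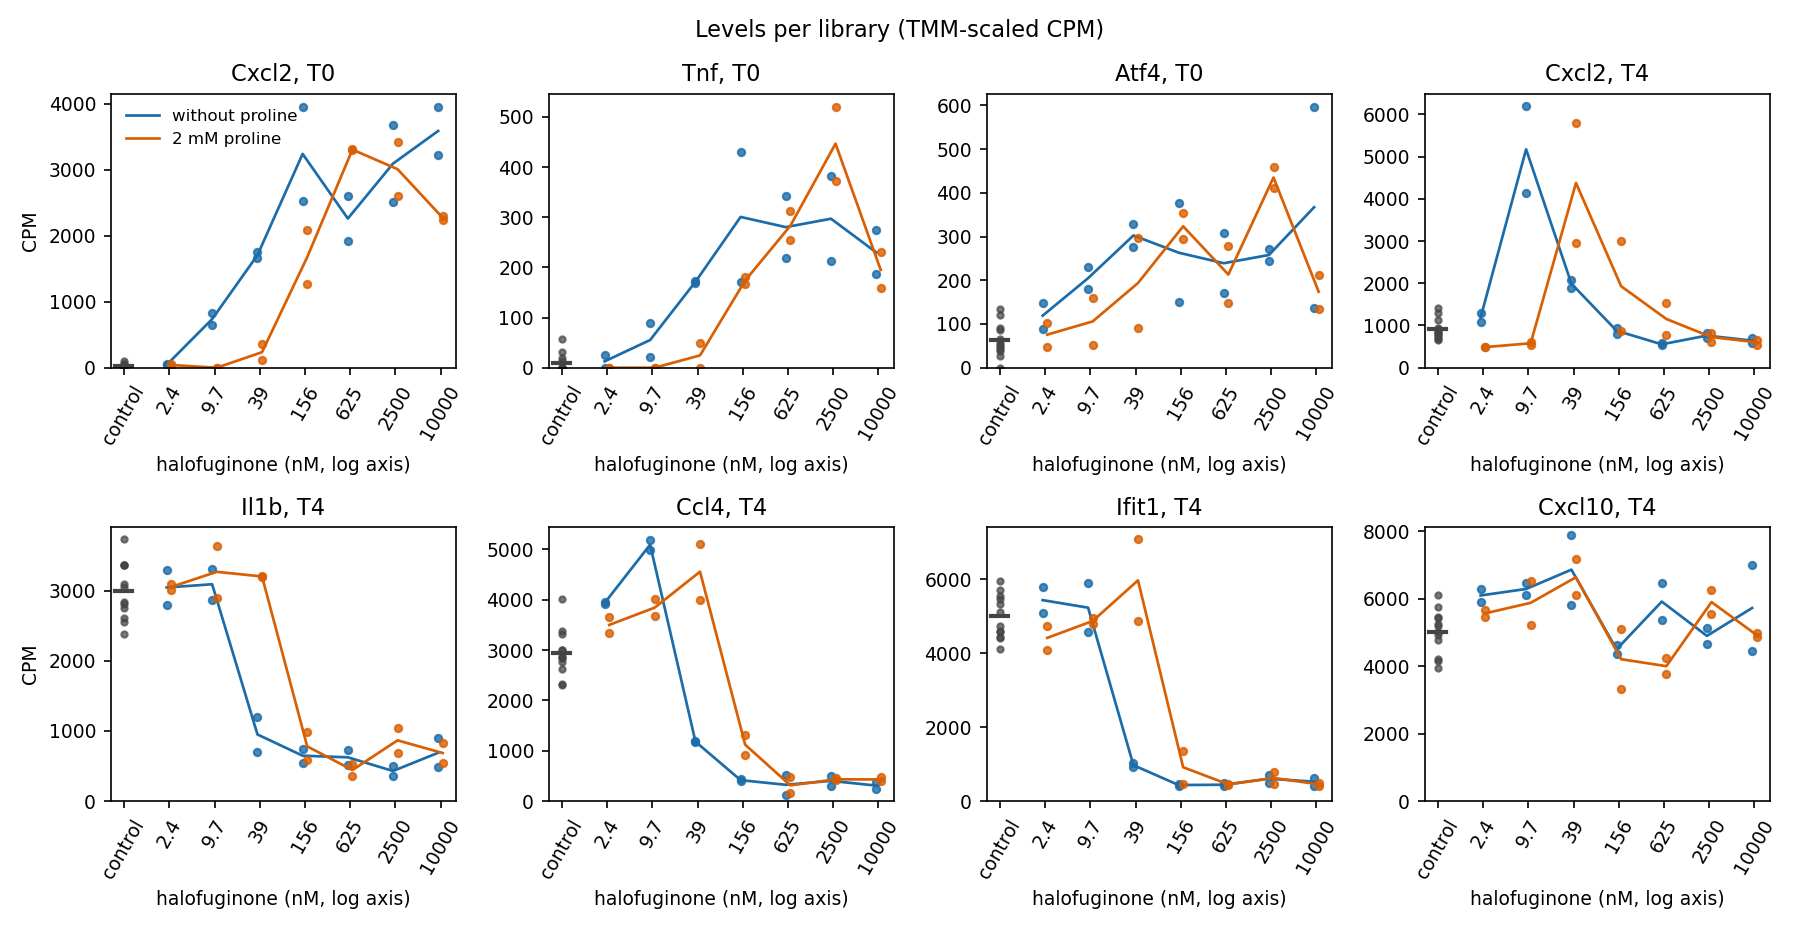
Expression of Cxcl2, Tnf and Atf4 at T0 and of Cxcl2, Il1b, Ccl4, Ifit1 and Cxcl10 at T4 (TMM-scaled CPM per library) in controls and by halofuginone dose (nM) with and without 2 mM proline, with each point 1 library. Cxcl2 at T0 runs from 28.0 CPM in controls to 2979 CPM at the 3 highest doses, and Ifit1 at T4 from 5003 to 528 CPM, while Cxcl10 at T4 stays near 5017 CPM.

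With proline, Cxcl2 rose at T0 in the 3 highest doses by 6.53 (SE 0.24), Il1b by 4.71 (SE 0.40), Tnf by 4.55 (SE 0.49), Atf3 by 2.98 (SE 0.26) and Atf4 by 1.97 (SE 0.36), all against the same 12 controls. In all, 214 genes rose and 276 fell (158 and 420 without the filter). All 12 immediate early genes rose (12 when adjusted over the list alone), as did 15 of 19 inflammatory genes (17 higher and 1 lower when adjusted over the list alone), 9 of 10 targets of ATF4 (9) and 4 of 5 TGF-beta response genes (4), while 72 of 77 ribosomal protein mRNAs fell (73). These 5 list calls held with an estimated correlation, and the filter favours the counts of risers here too. Macrophage identity genes, 9 of 15 lower (9), passed camera (adjusted p = 0.0346), but adjusted p = 0.109 with an estimated correlation. Both arms called 134 genes higher and 207 lower, where 31.8 and 64.7 would be shared by independent lists. No gene was shared in simulations where neither arm changed, but such arms offer few calls to share, so this is no measure of overlap from shared controls. With controls split so that the arms shared none, 114 and 166 were shared.

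A direct test of proline at T0, across the 3 highest doses, called 2 genes. Ncor1, a corepressor of nuclear receptors, was at 219 with and 74.2 CPM without proline (2.84, SE 0.67, adjusted p = 0.0320), and the protease inhibitor gene Serpinb6a at 294 and 46.0 CPM (2.39, SE 0.53, adjusted p = 0.0229), in 6 libraries against 6. DESeq2 called 0, and 111 genes had an unadjusted p under 0.05. Camera called the immediate early list lower with proline (median -0.39 over 12 genes, adjusted p = 0.00156), but adjusted p = 0.2 with an estimated correlation. At T1 and at T4 edgeR called 0 genes, with 117 and 140 at an unadjusted p under 0.05, and DESeq2 called 0 and 0. There Il1b differed by 0.08 (SE 0.21) and 0.19 (SE 0.22), and Cxcl10 by -0.20 (SE 0.23) and -0.14 (SE 0.14). Simulated 4-fold changes were recovered in 88.5% and 2-fold changes in 39.3% of genes in this comparison at T4, so smaller differences were mostly not detectable at this depth. These simulations changed many genes at once, and recovery can be lower where few genes change.

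After LPS, at T1, halofuginone lowered Il1b from 2399 ± 340 to 792 CPM (log2 fold change -1.35, SE 0.17, adjusted p = 7.07e-10, 6 libraries against 12), Ccl4 (-0.91, SE 0.18), Cd14 (-1.94, SE 0.34) and the complement gene C1qc (-3.13, SE 0.63). Rsad2 (-4.06, SE 0.50) and Ifit1 (-2.51, SE 0.46) fell further. Tnf was at 417 against 727 CPM (-0.51, SE 0.22, adjusted p = 0.0601) and Cxcl10 at 765 against 817 CPM (0.17, SE 0.19, adjusted p = 0.510). Immediate early factors rose, among them Ier2 (2.71, SE 0.52), Egr1 (2.37, SE 0.24), Jun (2.27, SE 0.26) and Fos (2.24, SE 0.41), and so did Ifrd1 (3.57, SE 0.32), Atf3 (2.37, SE 0.27), Atf4 (251 against 67.4 CPM, adjusted p = 0.000359) and Ddit3 (2.59, SE 0.65). The largest rises were in small nuclear and repeat RNAs, Rnu6 (4.54, SE 0.25) and Rn4.5s (4.08, SE 0.30). Of 1066 genes 118 rose and 248 fell, and without a filter on low counts 32 and 501.

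Immediate early genes rose in 13 of 16 (13 when adjusted over the list alone, median 1.17) and targets of ATF4 in 4 of 10 (4, median 0.83), while ribosomal protein mRNAs fell in 62 and rose in 1 of 76 (68 and 1, median -1.43). These calls held with an estimated correlation. Macrophage identity genes fell in 8 and rose in 1 of 15 (8 and 1), with camera's adjusted p = 0.0370 but adjusted p = 0.117 with an estimated correlation. The inflammatory list split, with 4 higher (Cd83 at 1.17, Ier3 at 2.16) and 6 lower of 30 (4 and 6 when adjusted over the list alone). Its median was -0.14 while camera's direction was upward (adjusted p = 0.790). Of 13 interferon-stimulated genes 4 fell (4, adjusted p = 0.244). With proline 162 genes rose and 251 fell at T1 (35 and 472 without the filter), with Il1b at -1.27 (SE 0.17), Ccl4 at -1.42 (SE 0.19), Rsad2 at -1.91 (SE 0.29) and Atf4 at 1.54 (SE 0.43). Targets of ATF4 rose in 5 of 10 (5 when adjusted over the list alone), immediate early genes rose in 11 and fell in 1 of 16 (13 and 1), and ribosomal protein mRNAs fell in 64 and rose in 1 of 76 (69 and 1). Macrophage identity genes fell in 9 of 15 (10 when adjusted over the list alone, camera adjusted p = 0.0156, but adjusted p = 0.0671 with an estimated correlation). Both arms called 78 genes higher and 184 lower (17.9 and 58.4 for independent lists, 68 and 156 with split controls).

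By T4 halofuginone had divided the LPS response. Ifit1 fell from 5003 ± 597 to 528 ± 124 CPM (log2 fold change -2.85, SE 0.18, adjusted p = 9.64e-26, 6 libraries against 12), Ccl4 by 2.74 (SE 0.20, 347 against 2942 CPM), Ccl5 by 2.61 (SE 0.20), Rsad2 by 2.05 (SE 0.14), Il1b from 2993 to 582 CPM (-1.97, SE 0.17) and Ccl3 by 1.88 (SE 0.20). Il6, which drives the acute phase response, fell by 0.95 (SE 0.37, adjusted p = 0.0253). Ifit2, a relative of Ifit1, rose by 1.14 (SE 0.13, 4431 against 2595 CPM), and Egr1 (4.92, SE 0.64), Jun (2.10, SE 0.50) and Ppp1r15a (2.51, SE 0.36), whose product restores translation after stress, rose too. Cxcl10 was at 5511 against 5017 CPM (0.53, SE 0.12, adjusted p = 0.000115), a fitted rise larger than these levels give, so its size depends on the scaling. Tnf (-0.44, SE 0.30, adjusted p = 0.208), Il12b (-0.34, SE 0.35, adjusted p = 0.412), Nos2 (0.43, SE 0.53, adjusted p = 0.502) and Atf4 (-0.25, SE 0.62, adjusted p = 0.753) did not pass. Ifnb1 passed (adjusted p = 0.00141) on 10 counts in the treated and 2 in the control libraries. Of 1315 genes 251 rose and 467 fell, and without a filter on low counts 96 and 772.

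Ribosomal protein mRNAs fell in 73 and rose in 1 of 76 at T4 (74 and 1 when adjusted over the list alone, median -2.51), for example Rpl17 (-3.80, SE 0.40), Rpl10 (-3.69, SE 0.41) and Rps29 (-2.77, SE 0.31). Macrophage identity genes fell in 11 of 16 (11 when adjusted over the list alone, median -0.997), among them Lgals3 (-2.55), Cd14 (-2.53) and the Fc receptor chain Fcer1g (-2.51). Both calls held with an estimated correlation (adjusted p = 4.78e-05 and 0.0278). Genes with a short exon length fell more in general at T4, also with ribosomal protein genes left out (Spearman rho 0.383). Macrophage identity genes were not matched for exon length, so a fall beyond this trend was not tested for them. Inflammatory genes split into 4 higher and 13 lower of 35 (4 and 13, adjusted p = 0.393), and interferon-stimulated genes into 9 higher and 12 lower of 39 (10 and 12), with a median of -0.07 where camera's direction was upward (adjusted p = 0.804). Lysosomal genes fell in 8 of 13 (8, adjusted p = 0.193), with Ctsb at -1.56, and the cell cycle inhibitor Cdkn1a fell by 2.16 (SE 0.25). Immediate early genes had a median of 0.07 over 8, which became -0.11 under median-of-ratios scaling. That scaling moved the median of all genes from -0.23 to -0.41 in this comparison and from -0.20 to -0.38 with proline. Rnu6 (6.27) and Rn4.5s (4.31) led the rises here too.

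With proline, at the 3 highest doses at T4, Ifit1 was at -2.88 (SE 0.18), Ccl4 at -2.45 (SE 0.19), Il1b at -1.79 (SE 0.17) and Il6 at -2.54 (SE 0.50), where the direct difference between the arms was -1.59 (SE 0.66, adjusted p = 0.312). Nos2, which makes nitric oxide, rose by 1.41 (SE 0.44, adjusted p = 0.00524), and so did the RNA sensor Ddx58 (1.34, SE 0.20), while Cmpk2 fell by 1.60 (SE 0.20) and Rps29 by 4.33 (SE 0.39). Cxcl10 was at 0.39 (SE 0.12, adjusted p = 0.00511), and without a filter on low counts at -0.05. In all, 244 genes rose and 440 fell (75 and 641 without the filter). Ribosomal protein mRNAs fell in 72 and rose in 1 of 76 (72 and 1 when adjusted over the list alone, median -2.38, a call that held with an estimated correlation), and macrophage identity genes fell in 10 of 16 (11 when adjusted over the list alone, adjusted p = 0.0756). Inflammatory genes rose in 8 and fell in 14 of 35 (9 and 14), and interferon-stimulated genes rose in 8 and fell in 11 of 39 (8 and 11). Both arms called 158 genes higher and 383 lower, with 1 called in opposite directions (46.6 and 156 for independent lists, 118 and 348 with split controls).

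Whether halofuginone changed the LPS response was tested as the change from control at T1 or T4 less that at T0, so an effect already present at T0 enters each value. At T1 Cxcl2 (-6.65, SE 0.31), Cxcl3 (-6.46, SE 0.60), Ccl4 (-5.78, SE 0.36), Il1b (-5.70, SE 0.40) and Tnf (-5.04, SE 0.49) rose far less in treated than in control cells, from a T0 level that was already high in treated cells. At T4 the values were -7.81 (SE 0.36) for Ccl4, -7.00 (SE 0.34) for Cxcl2, -6.53 (SE 0.40) for Il1b, -4.81 (SE 0.24) for Nfkbia and -2.69 (SE 0.69) for Atf4. Halofuginone had raised all of these genes at T0, and Atf4 did not differ from control at T4 by the threshold. Large decreases here therefore do not by themselves show a loss of LPS induction. Cxcl10 was at 0.05 (adjusted p = 0.870), but its few T0 counts in treated and control libraries leave this change poorly determined. Of 1084 genes at T1, 3 were higher and 63 lower, and of 1468 at T4, 20 and 239, while with proline 7 and 224 of 1486 passed at T4. Inflammatory genes were lower in 16 of 27 at T1 (18 when adjusted over the list alone, median -2.53), 22 of 35 at T4 (23, median -3.05) and 21 of 34 with proline (21, median -2.65). Immediate early genes were lower in 8 of 14 (9, median -2.41), 9 of 12 (10, median -3.19) and 6 of 10 (8, median -3.11), and targets of ATF4 in 5 of 8 at T4 (5, median -2.75). All of these calls held with an estimated correlation. At T4 camera also called p53 targets, 3 of 3 lower (3), but adjusted p = 0.0658 with an estimated correlation. Ribosomal protein mRNAs were lower in 32 of 78 (39), but adjusted p = 0.172 with an estimated correlation, and with proline in 30 of 78 (41), but adjusted p = 0.406 with an estimated correlation. Median-of-ratios scaling moved the median of all genes from -0.46 to -0.27, with 38 genes higher and 189 lower, and with proline from -0.54 to -0.28, with 19 and 152.

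Slopes per 10-fold dose, over the 14 treated libraries of a time and arm without controls, gave the direction within the treated range. At T0 the immediate early factor Egr1 rose by 1.73 log2 per 10-fold dose (SE 0.22), Kdm6b by 1.33 (SE 0.16) and Atf3 by 0.97 (SE 0.11), while Rps25 fell by 0.80 (SE 0.15). At T4 Ccl4 fell by 1.22 (SE 0.15), the antigen-presentation gene B2m by 1.09 (SE 0.13), Ifit1 by 1.04 (SE 0.14) and Il1b by 0.72 (SE 0.11), while Cxcl10 stayed at -0.01 (SE 0.08, adjusted p = 0.924). At T1 the inflammatory genes Tnfsf9 (-0.85, SE 0.15), Cxcl1 (-0.64, SE 0.15) and Tnf (-0.37, SE 0.11) fell with dose. The mean level of Tnf at 9.7 nM at T1 lay above that of controls, so its slope is no measure of a fall below control. With proline at T0, Kdm6b (1.94, SE 0.23), Cxcl2 (1.85, SE 0.37), Ifrd1 (1.70, SE 0.17) and Il1b (1.49, SE 0.30) rose. Genes past the threshold numbered 145 of 368 at T0, 85 of 317 at T1 and 118 of 329 at T4, and with proline 220 of 449, 189 of 465 and 279 of 508. Without the first 2.4 nM library at T1 the 85 became 43, and without the second 2500 nM library at T4 the 118 became 185.

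At T0 immediate early genes rose with dose in 9 of 9 (9 when adjusted over the list alone, adjusted p = 0.0374 with an estimated correlation) and ribosomal protein mRNAs fell in 37 of 57 (41, adjusted p = 0.0218 with an estimated correlation). Inflammatory genes rose in 7 of 8 (7), a camera call with adjusted p = 0.117 with an estimated correlation. In all slope fits, genes low at some doses could pass the filter only through doses where they were high. Counts such as 9 of 9 are therefore favoured by the filter. With proline, ribosomal protein mRNAs fell with dose in 56 of 69 at T0 (61) and 47 of 67 at T1 (54 lower and 2 higher), with adjusted p = 0.00287 and 0.0106 with an estimated correlation. The other camera calls on slopes were lost with an estimated correlation. At T1 these were inflammatory genes (1 higher and 7 lower of 17, 2 and 9 when adjusted over the list alone, adjusted p = 0.363) and ribosomal protein mRNAs (1 and 17 of 39, 1 and 19 alone, adjusted p = 0.108), and at T4 inflammatory genes (1 and 13 of 22, 1 and 13 alone, adjusted p = 0.218) and ribosomal protein mRNAs (5 lower of 9, 7 alone, adjusted p = 0.218). With proline they were inflammatory (6 of 6 higher, 6 alone, adjusted p = 0.134), immediate early (8 of 8, 8 alone, adjusted p = 0.0845) and TGF-beta response genes (3 of 3, 3 alone, adjusted p = 0.0845) at T0. At T1 they were targets of ATF4 (2 of 4, 3 alone, adjusted p = 0.154) and immediate early genes (2 of 10, 2 alone, adjusted p = 0.441), and at T4 ribosomal protein mRNAs (44 of 53 lower, 46 lower and 1 higher alone, adjusted p = 0.233), all adjusted p-values being those with an estimated correlation.

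Single doses, compared with control after the data were examined, give values for proline at lower doses. At T0 and 9.7 nM, Cxcl2 was at 737 ± 124 CPM without proline and had 0 counts in both libraries with it, and at 39 nM it was at 1706 ± 64.2 and 236 ± 178 CPM (2 libraries each). At T4 and 39 nM, the 2 Ifit1 levels were 920 and 1029 CPM without proline and 4864 and 7083 CPM with it (2.34, SE 0.30, adjusted p = 1.40e-08), Rsad2 differed by 1.86 (SE 0.25), Ccl5 by 2.06 (SE 0.33) and Il1b by 1.49 (SE 0.30). At T4 and 9.7 nM the difference was the other way for Cxcl2 (-3.31, SE 0.39), Cxcl1 (-3.76, SE 0.65) and Tnf (-2.14, SE 0.42), each higher without proline. Direct tests with against without proline at T4 called 0 genes at 2.4 nM, 14 at 9.7, 150 at 39, 1 at 156 and 0 at each of 625, 2500 and 10000 nM in edgeR. At an unadjusted p under 0.05 those with 0 calls had 43, 107, 116 and 119 genes, and DESeq2 was not run on single doses. The highest counts at the other times were at 9.7 nM, with 27 genes at T0 and 19 at T1. At T0, 12 genes passed at 39 nM and 4 at 156 nM, with 0 at 2.4, 625, 2500 and 10000 nM (38, 74, 74 and 122 at an unadjusted p under 0.05). At T1, 0 passed at 2.4, 39, 156, 625, 2500 and 10000 nM (47, 133, 85, 79, 100 and 95).

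**Figure D3:**
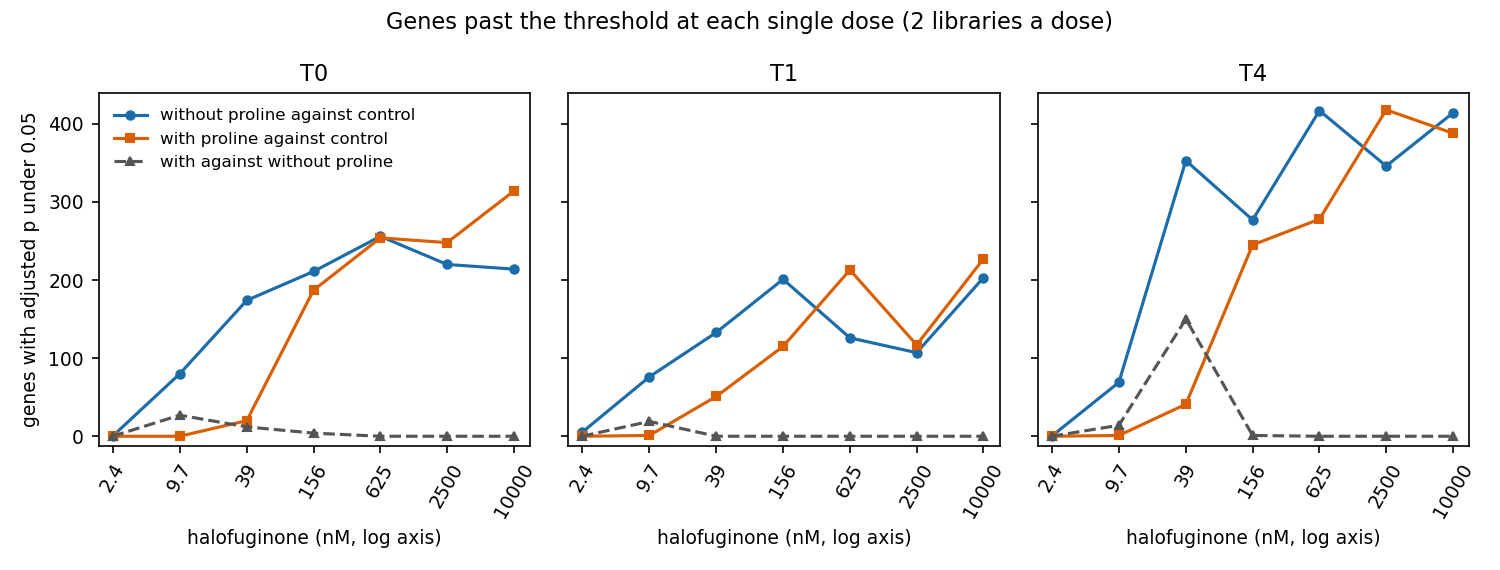
Number of genes with an edgeR adjusted p under 0.05 at each halofuginone dose (nM, log axis) at T0, T1 and T4, with 1 line each for halofuginone against control, halofuginone with 2 mM proline against control, and with against without proline. At T4 the lines without and with proline stand at 353 and 41 genes at 39 nM and at 414 and 388 at 10000 nM.

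**Figure D4:**
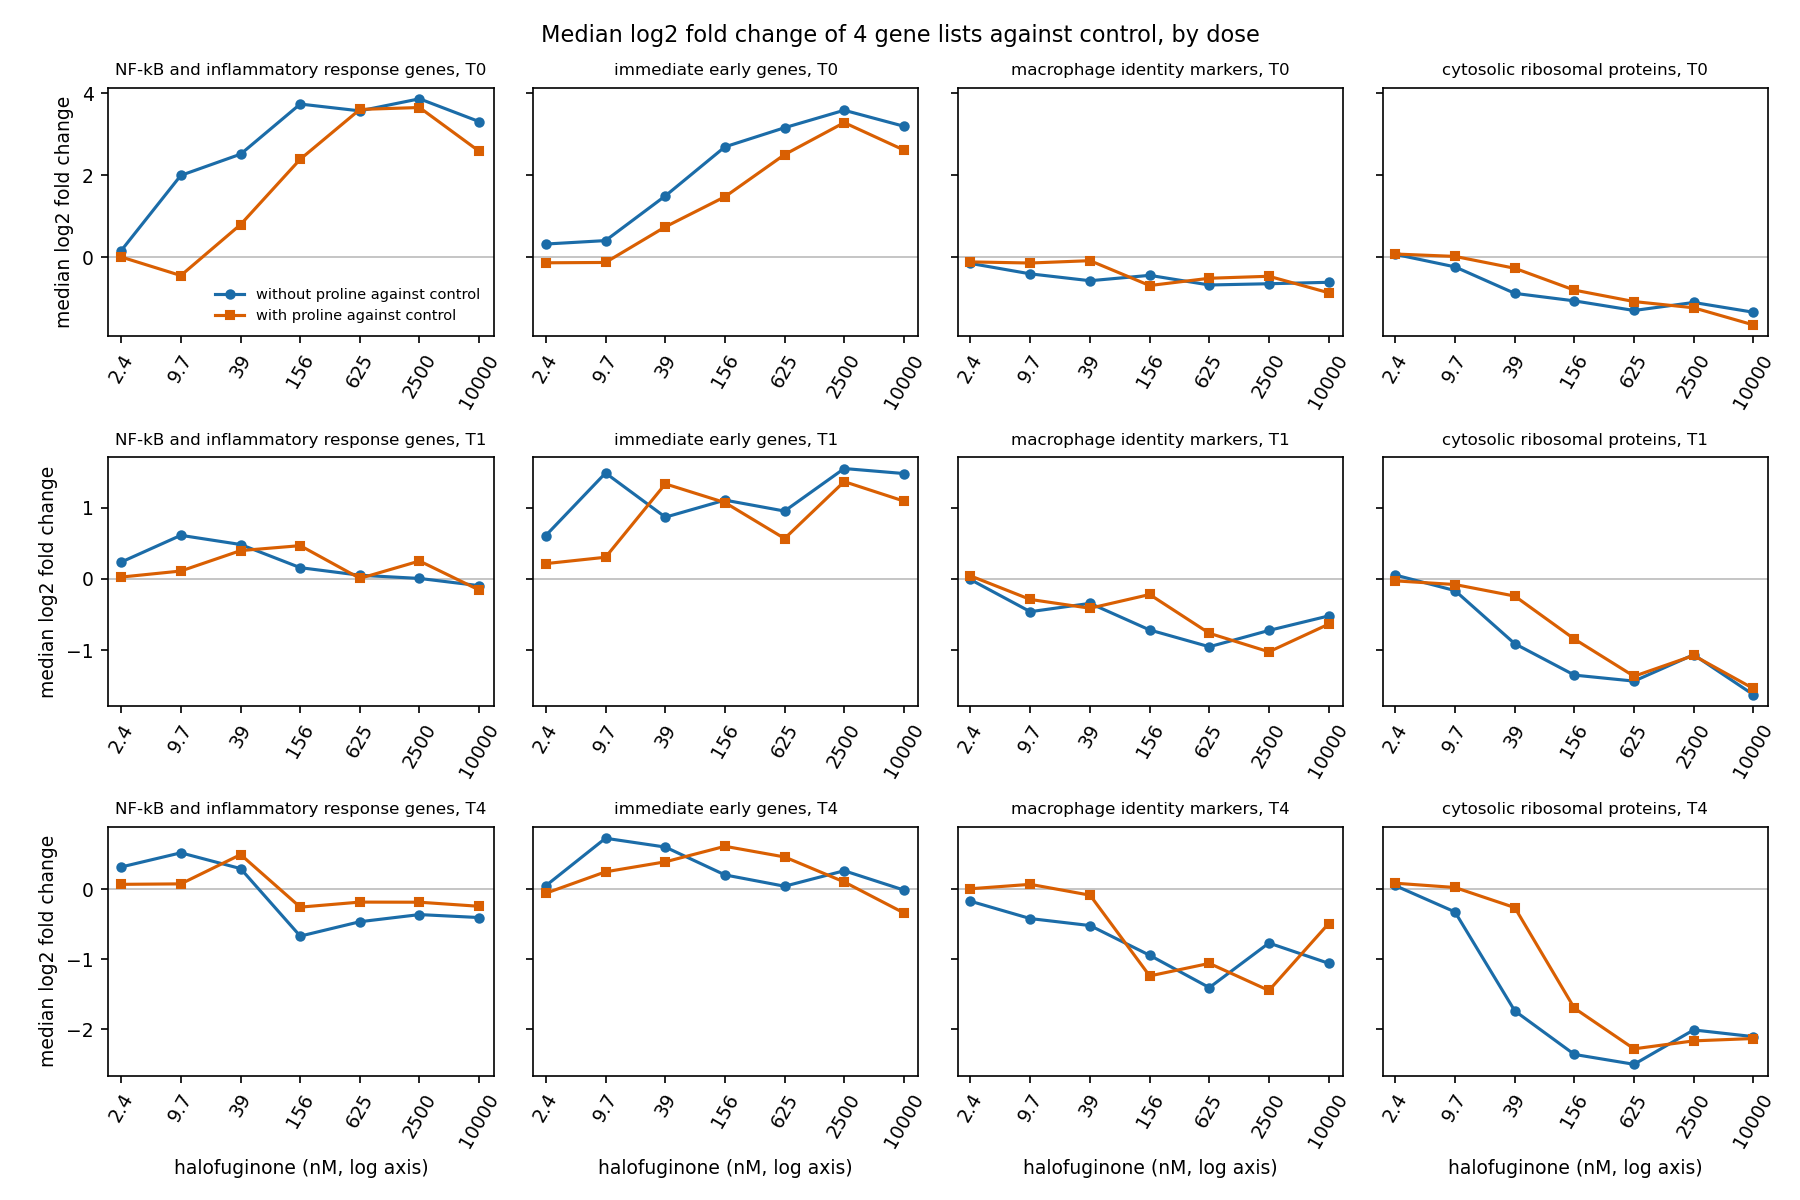
Median log2 fold change against control of inflammatory, immediate early, macrophage identity and ribosomal protein genes (y axis, shared within a row) by halofuginone dose (nM, log axis) at T0, T1 and T4, with lines for halofuginone with and without 2 mM proline. The inflammatory median at T0 is 2.00 at 9.7 nM without proline and -0.45 with it, and the ribosomal protein median at T4 is -1.74 and -0.26 at 39 nM; immediate early medians near 0 at T4 change sign with the scaling.

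Several fixed lists had too few counts for a list test. Cell cycle genes held 3884 counts over the 120 libraries with 1 gene tested at T1, proline metabolism genes 687 with 1 tested at T4, and cholesterol biosynthesis genes 1191 with none tested. Markers of dendritic cells had 500 counts, of fibroblasts 217, of T and NK cells 47, of B cells 4 and of erythroid and mast cells 1, with none tested. Neutrophil markers summed to 374 ± 82.2 CPM in T0 controls and 114 ± 90.7 CPM with halofuginone, and S100a9 (-3.47, SE 0.77) and S100a8 (-3.27, SE 0.85) fell on 4 counts each in the treated libraries. No mitochondrially encoded symbol was in the table.

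On the GRCm38 (mm10) genome, Cxcl2 lies on chromosome 5 from 90903871 to 90905938 and Cxcl10 on the same chromosome from 92346638 to 92348889. Il1b lies on chromosome 2 from 129364570 to 129371139, Ccl4 on chromosome 11 from 83662584 to 83664683, Ifit1 on chromosome 19 from 34640871 to 34650009, Atf4 on chromosome 15 from 80255184 to 80257541 and Eprs on chromosome 1 from 185363044 to 185428360. All 7 are annotated as protein-coding genes, and the 3′ counts were given per gene, not per exon.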

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

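The tests of transcript length, of endotoxin at 9.7 nM and at 625 nM and above, of a common share by interferon-stimulated genes, of a fixed share of cells and the splits of LPS at T1 were chosen only after the result was seen. The other tests here were chosen before the data were examined, except that a bootstrap bound was added later to the rule for late genes, with the same outcome. Beforehand, an excess over other LPS-raised genes was to count against a common share, and a split count of 0 was to be read like any other. After the values were seen, neither was used to decide alone, since a common share would also raise most the genes that LPS raises most, and every split has at least 0 genes. The test of a fixed share of cells first used the spread of the changes, which only restates the pattern, and then the genes called higher. The depth test at T0 first used only genes that passed the filter after thinning, and was then run over all inflammatory genes tested at full depth, and the split and simulated controls for rho were added, both after the first values were seen.

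Ribosomal protein mRNAs fell with halofuginone at T4 in 73 of 76 genes. Genes with a short exon length fell more in general, with a Spearman rho of 0.428 between exon length and log2 fold change. Ribosomal protein genes lay 1.33 log2 below genes matched for exon length and level (difference -1.33, 95% interval -1.79 to -1.05). Exon length here joins all annotated exons of a gene, such as 6256 bases for Rps24, and can exceed that of the mRNA measured. The match therefore cannot exclude mRNA length as a cause. Lower depth cannot account for the fall, since the median of the 38 ribosomal protein genes then tested was -2.29 with all libraries thinned to 9954 counts outside Rn45s (-2.43 over all 76). Other mRNAs with a 5′ terminal oligopyrimidine tract differed from their matched genes by 0.0756 (interval -0.50 to 1.21, 13 genes), so an effect on that whole class cannot be told apart from none. Whether these mRNAs are degraded or make up a smaller share of poly(A) RNA stays open.

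Inflammatory mRNAs rose with halofuginone at T0. Endotoxin in the compound may be suspected, but at 9.7 nM the inflammatory list lay at -1.39 with proline relative to without, lower in 17 of 19 genes, and proline would not remove an endotoxin. At 625 nM and above the rho between the LPS change at T1 and the halofuginone change at T0, which share their T0 controls, was 0.666 (interval 0.478 to 0.785; covariance 2.50), and 0.639 and 0.677 with those controls split (covariances 2.59 and 2.56), against a highest rho of -0.0573 and a mean covariance of -0.282 in 20 simulations of unchanged groups, which, with the exposure at T0 not known, leaves endotoxin unable to be told apart from a response of the cells. Halofuginone at T0 reached 0.467 of the LPS rise at T1 in 28 summed inflammatory genes but -0.0248 of it in 12 interferon-stimulated genes (difference -0.491, interval -0.564 to -0.421). For the median gene the difference was -0.413 (interval -0.537 to -0.300). The share reached was therefore not the same in the 2 lists. However, the interferon-stimulated list was also lower with halofuginone after LPS at T1, at 2313 ± 502 against 3746 ± 252 CPM in controls. With that fall, and the exposure at T0 not known, the low share cannot exclude an LPS-like response. The excess of listed over other LPS-raised genes, 2.60 log2, does not decide by itself. Lower depth is argued against by a median of 3.30 (interval 1.44 to 4.22) over the 19 inflammatory genes tested at full depth, 18 of them above 0, with libraries thinned to 12852 counts outside Rn45s.

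LPS-raised mRNAs were unequally changed by halofuginone at T4, with 62 lower and 26 higher of 132 tested genes that LPS had raised by over 4-fold. A fixed share of cells that stopped responding would lower these genes in absolute amount, but the counts give relative levels only. Upward calls numbered 26, and 21 with median-of-ratios scaling, with a highest change of 1.44 log2. Their number depends on the scaling, so this test cannot exclude a fixed share of cells. Lower depth is argued against by a spread of log2 changes of 4.94 times the median standard error over 104 genes with libraries thinned to 9954 counts outside Rn45s (5.38 times without thinning). Late LPS genes differed from early ones by 0.0908 (interval -0.33 to 0.60), which argues against greater loss of late genes. What separates Ifit1 from Ifit2 and Cxcl10 stays open.

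The change in the LPS response passed in 66 genes at T1, 259 at T4 and 231 at T4 with proline. Each value, for genes and lists alike, includes the effect of halofuginone at T0. Decreases of genes already raised there do not by themselves show a loss of LPS induction. At T1 the values were -6.65 for Cxcl2, -6.46 for Cxcl3, -6.17 for Tnfsf9, -6.15 for Irg1, -5.78 for Ccl4, -5.70 for Il1b, -5.04 for Tnf and 2.09 for Txnip. At T4 the decreases were -8.20 for Ccl7, -7.81 for Ccl4, -7.43 for Kdm6b, -7.00 for Cxcl2, -6.68 for Ccl3, -6.53 for Il1b, -5.19 for Tnf, -4.56 for Ddit3 and -2.69 for Atf4. The increases there were 3.78 for Fam46a, 3.53 for Ifit2, 3.49 for Tcp1, 2.90 for Bfar and 1.86 for Rnu6. With proline at T4 the decreases were -7.08 for Ccl7, -7.02 for Ccl4, -6.83 for Il1b, -6.65 for Cxcl2, -5.91 for Ccl3, -5.75 for Basp1, -4.66 for Tnf and -1.94 for Atf4, and the increases 2.05 for Rnu6, 1.93 for Ctnna1, 1.58 for Stxbp3a and 0.47 for Rn45s.

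As lists, inflammatory genes had medians of -2.53 at T1, -3.05 at T4 and -2.65 at T4 with proline, and immediate early genes -2.41, -3.19 and -3.11. At T4 targets of ATF4 had a median of -2.75, p53 targets -1.75 and ribosomal protein mRNAs -1.24, and with proline ribosomal protein mRNAs -1.26. With an estimated correlation the camera calls of p53 targets (adjusted p = 0.0658) and of ribosomal protein mRNAs (adjusted p = 0.172, and 0.406 with proline) were lost.

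Libraries were also split at random, keeping the group sizes, and genes were counted again. The real split was the only 1 of 100 with as many genes for LPS at T1 (187, highest other 94), LPS at T4 (540, 4), halofuginone at T0 (433, 105) and T1 (366, 196), and halofuginone with proline at T0 (490, 102) and T1 (413, 219). At T4 it was 1 of 61 for halofuginone (718, 236) and for halofuginone with proline (684, 11). For the change in the LPS response it was 2 of 100 at T1 (66, highest other 73), 1 of 100 at T4 (259, 145) and 1 of 100 with proline (231, 208). These splits mix treated and control libraries within each time, so they also remove the effect at T0. They do not test the change in the response apart from a steady effect of halofuginone. For proline added to halofuginone at T0 chance cannot be excluded, as 7 of 100 splits had as many as the 2 genes (highest other 9). At T1 and T4 the real count of 0 is met by every split, 100 of 100 (highest other 14) and 61 of 61 (highest other 6), so the splits decide nothing there.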

How the results depend on the processing

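The tests without libraries under 30000 counts and without ribosomal and small RNA genes were added only after the result was seen. Of 20471 values of named genes under another setting, 19509 stayed the same, 922 became weaker, 35 stronger and 5 reversed. Where a value moved or reversed, the cause was not tested. Proline added to halofuginone at T0 gave 1 gene with median-of-ratios size factors, 4 without a filter, 0 with DESeq2 and 1 without 10000 nM. At T1 it gave 2 without a filter and 1 without low-depth libraries, and at T4 1 each without a filter, with the block, without ribosomal and small RNA genes and without low-depth libraries. With replicate number as a block, halofuginone gave 236, 208 and 423 genes at T0, T1 and T4, and with proline 260, 216 and 391. In these fits no treated library shares a number with the controls numbered above 2, so each of those controls takes its own block. The contrast then rests on controls 1 and 2, so the block cannot be told apart from the loss of the other controls. LPS gave 195 and 549, the change in the LPS response 60, 231 and 221, slopes 144, 78 and 113 and with proline 216, 184 and 273, and added proline 3 at T0. The block moved camera's adjusted p across the threshold in 5 cases. With halofuginone it went from 0.0370 to 0.0537 (T1) and from 0.0223 to 0.0616 (T4) for macrophage identity genes and from 0.0579 to 0.0429 for p53 targets at T0. These contrasts too rest on controls 1 and 2 once blocked. It went from 0.0714 to 0.0428 for TGF-beta response genes in LPS at T1 and from 0.0515 to 0.0402 for immediate early genes with added proline at T1. By the rule used here the numbers do not pair the libraries, since not every pair's correlation is over 0.1. Deviations of libraries with the same number at matched dose correlated with medians of 0.0224, 0.00332 and -0.0216 at T0, T1 and T4. Across times the medians were 0.0884 for the same treatment (18 of 42 over 0.1) and 0.101 for controls with the same number (18 of 36), against -0.0108 for other numbers (49 of 396), and 12 of 36 controls matched best with their own number, where shuffled numbers gave 3.00 on average and at most 9. Control 9 had the lowest Rn45s share at all 3 times (38.9, 35.7 and 27.0%). These values hint that control numbers share something across times, which no label states. Without a filter LPS gave 321 genes at T1 and 2215 at T4, the change in the LPS response at T4 148, and the slopes 219, 181 and 679 at T0, T1 and T4 and 816 with proline at T4. Without low-depth libraries the slopes at T1 gave 162. List calls numbered 57, against 35 with an estimated correlation and 148 with fry. Total counts with proline at T1 differed by -20455 without 10000 nM (adjusted p = 0.0557, permutation test).

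Signs reversed without a filter for Mdm2 at T1 (-0.0284), Cxcl10 with proline at T4 (-0.0505) and its slope there (-0.12). Without the first or second 625 nM library at T4, Hk1 was at -0.28 or 2.09. Without the first or second such library with proline, Calr there was at -0.00567 or 0.88.

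Leaving out 1 library gave 418 to 487 genes for halofuginone at T0, 320 to 390 at T1 and 651 to 763 at T4, and with proline 459 to 501, 368 to 430 and 558 to 701. For added proline the counts ran from 0 (without the second 10000 nM library) to 5 (without the second 10000 nM library with proline) at T0, 0 to 4 (without the second 625 nM library) at T1 and 0 to 7 (without the second 2500 nM library) at T4. Slopes gave 99 to 155 at T0, 43 to 120 at T1 (without the first 2.4 nM or the second 2500 nM library) and 83 to 185 at T4 (likewise), and with proline 193 to 235, 154 to 201 and 237 to 324. LPS gave 176 to 205 and 517 to 569, and the change in the LPS response 54 to 80 at T1, 193 to 270 at T4 and 199 to 265 with proline.

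Median-of-ratios scaling moved the share of higher genes from 69.0 to 82.9% for LPS at T1, from 48.0 to 59.2% for LPS at T4, from 51.8 to 33.7% for slopes at T1 and from 45.9 to 33.2% for slopes with proline at T4. DESeq2 gave 79.5, 59.0, 38.7 and 34.4% for these. Without a filter the share of higher genes went to 81.3% for LPS at T1. For halofuginone it went from 38.8 to 22.6% at T0, from 32.2 to 6.00% at T1 and from 35.0 to 11.1% at T4, and with proline from 43.7 to 27.3%, from 39.2 to 6.90% and from 35.7 to 10.5%. For slopes it went to 26.9, 17.1 and 10.3%, and with proline to 38.0, 14.5 and 17.8%. It went from 39.2 to 26.8% with proline at T1 without low-depth libraries. Slopes at T1 without ribosomal and small RNA genes gave 31 higher and 55 lower. Median-of-ratios scaling moved the median of all genes from -0.21 to -0.32 for halofuginone at T1 and from -0.07 to -0.19 with proline. Medians changed sign for NRF2 targets in LPS at T4, hypoxia genes in the change at T1, interferon, chaperone, heat shock and hypoxia genes in the change with proline at T4, interferon genes in slopes with proline at T4, inflammatory genes with proline at T1 and immediate early genes with proline at T4.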

Other observations

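Both tests of proline against a lower dose were chosen only after the result was seen.

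Levels of a few genes at 9.7 nM are given here, and were not tested against the higher doses. At T1, Cxcl2 was at 10404 ± 860 CPM at 9.7 nM without proline and 3516 ± 541 CPM with it, against 3321 ± 598 CPM in controls. Tnf at T1 was at 1521 ± 24.6 and 873 ± 35.3 CPM, against 727 CPM in controls, and at T4 at 1605 ± 164 and 407 ± 6.39 CPM, against 332 CPM. Il1b at T1 went the other way, at 1297 ± 8.24 CPM without and 2435 ± 368 CPM with proline. Each group has 2 libraries, and these doses and genes were chosen after their values were seen.

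Summed levels follow the most abundant genes of a list and were not tested. Macrophage identity genes summed to 8298 ± 895 CPM in T4 controls and 2711 ± 310 CPM with halofuginone, and cell cycle genes to 423 ± 76.6 and 194 ± 99.9 CPM.

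A hypothesis is that proline acts like a lower dose of halofuginone, which competition for the same enzyme would give. At T4 the libraries at 39 nM with proline lay nearer to 9.7 nM than to 39 nM without proline, with a ratio of distances of 0.583 (0.559 to 0.606). Of the doses without proline they lay nearest to 2.4 nM (0.519 log2, against 0.567 log2 for 9.7 nM). Their distance to control was 0.567 log2 as well, so the distances alone do not separate a lower dose from a nearly absent effect. Against control, 39 nM with proline gave 20, 51 and 41 genes at T0, T1 and T4, while 9.7 nM with proline gave 0, 1 and 1 and 2.4 nM with proline 0, 0 and 0 (edgeR; 61, 41 and 59, and 50, 36 and 30 at an unadjusted p under 0.05), so halofuginone still acted at 39 nM with proline. At 156 nM the ratio was 0.963 (0.924 to 1.00), where a lower dose and no change in dose cannot be told apart. Across times, 15 of 18 groups with proline lay nearer to the next lower dose than to their own, but the doses above 156 nM also resemble each other, so these say less. Controls with proline alone would be needed to separate an effect of proline itself, and these were not used here because none carry that label.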
